A study of Homo sapiens with 76 samples.

How the data were processed

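H3K4me3 and H3K27me3 were measured in H1 human embryonic stem cells by chromatin immunoprecipitation and 2-colour tiling arrays. Per the labels, immunoprecipitated DNA was labelled with Cy3 and total genomic DNA with Cy5, and each mark was hybridised to 38 arrays of probes 50 nucleotides long. The groups are the 2 marks, and the array number says which part of the genome an array holds, so it does not number replicates. The deposited scanner files hold intensities of the 532 nm and 635 nm channels per probe, with no background column, per the file headers. 1 of these files has no header line, and its channels were told apart by the sign of the deposited ratio of the same array. The deposited value table holds log2 ratios of the 532 nm over the 635 nm channel. The method behind it is not given in the sources used here. Its values correlated with the log2 ratios computed here at 0.71 or more on each array, and its medians per array lay between -0.03 and 0.05, so its direction matches and the centring is near 0. Saturated spots were kept. They made up at most 0.147% of the total DNA channel of an array.

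The genome build is not given in the sources used here. Coordinates are those of the files, 1-based, and the highest position on chromosome 1 is 245440979. No annotation of that build was used. The table of gene names at hand belongs to GRCh38.p14, and it served only to count the protein-coding genes of each chromosome and to list the chromosomes of HOX genes. Promoter results and the gene lists set up beforehand were therefore not analysed here.

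For each probe, the log2 ratio of Cy3 over Cy5 intensity was taken and the median of its array subtracted, with no loess or quantile normalization, since many probes may carry signal. Tiling probes were averaged in bins of 1 kb with at least 5 probes (8 in the median), which gave 1654324 bins on 44 sequences. The rule planned for calling a bin was the smallest threshold at which bins below its negative number at most 0.05 of the bins above it. It called 0 bins for both marks, and a threshold of 2-fold (a mean log2 ratio above 1) was then used, chosen after seeing the data. Called bins were joined over gaps of up to 1 kb. Overlap of the marks was set against the product of their shares and against 1000 circular shifts along each sequence. Regions named in the text were chosen by a rule set before the data were examined: the 10 domains of at least 3 kb with the highest mean and the 10 longest, per mark and for bins with both marks, here applied to domains at 2-fold. The few with the highest rank are given in full. Control regions were compared by two-sided permutation tests with 100000 resamples, and also with limma with the number series of the scanner headings as a random block (consensus correlation 0.27, 75 arrays, since 1 file gives no number). Each series holds arrays of 1 mark only, so no value within a series compares the marks. Each array was also given a response, the slope of its control probes on the mean of the other arrays of the mark, which ran from 0.54 to 1.32 for H3K4me3 and from 0.49 to 1.24 for H3K27me3. Control windows of 500 bp and the tiling probes at the same coordinates correlated at r = 0.97 for each mark over 166 windows.

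The calling functions were tested on simulated data with planted domains on the probe positions of chromosomes 21 and 22, with the real probe values shuffled as noise, over 40982 bins. At 2-fold, of bins planted with a log2 ratio of 2, 96.7% were called for H3K4me3 and 100% for H3K27me3, of bins planted with 1, which is the threshold itself, 29.2% and 59.2%. Of bins with nothing planted, 0.0173% were called for H3K4me3 and 0.0396% for H3K27me3. Shuffling removes any likeness of neighbouring probes, so these shares hold for shuffled values and give no false-call rate for the real bins. With symmetric noise, 92.6% of the bins that the planned rule called for H3K4me3 were planted ones and 95.3% for H3K27me3. With the shuffled values as they were, 100% of the 183 bins it called for H3K4me3 and 54.7% of the 944 it called for H3K27me3 were planted ones. On the real bins the same rule called 0 for both marks, so the shuffled values do not stand for the real noise.

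The alternatives planned before the data were examined were an offset of 50 on both channels, scaling of arrays to one median absolute deviation (MAD), loess within arrays (span 0.3), the deposited values, a false discovery rate of 0.01, the median of probes, leaving out the dimmest and brightest 1% of probes, odd or even probes alone (at least 3 per bin), other bin widths and probe minimums, joining over 3 kb, correlation within arrays, and total DNA swapped between the sets. Added after seeing the data were scaling on the control regions, centring on random-sequence probes, thresholds of 1.5-fold and 3-fold, all tests of the control regions, of chromosomes and of array response, the swapped total DNA for the overlap, and other normalizations for the correlation, the strongest H3K4me3 bins, the summits and the named regions, the same bins followed through the settings, and 100 shifts of the H3K27me3 bins for H3K4me3 domains. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.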

Results

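Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark found at promoters of active and poised genes, and at lysine 27 (H3K27me3), the mark set by Polycomb repressive complex 2, were mapped by chromatin immunoprecipitation in H1 cells, an established line of human embryonic stem cells. For each mark, immunoprecipitated DNA labelled with Cy3 and total genomic DNA labelled with Cy5 were hybridised together to a set of 38 oligonucleotide arrays, 76 arrays in all. The arrays of a set hold different parts of the genome, so that each of the 14628301 tiling probes, spaced 100 bp apart in the median, was measured once per mark. The median intensity of an array lay between 336 and 1280 for H3K4me3 DNA and between 516 and 1575 for H3K27me3 DNA. Each array also carried 10 control regions of about 10 kb, tiled by 2735 probes, which gave 38 hybridisations of the same sequence per mark. Values below are log2 ratios of immunoprecipitated over total DNA, with the median of each array set to 0. The number of arrays limits their precision.

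The question put to the control regions was which mark each of them carries, and whether the difference exceeds the spread between arrays. The region that the files name after SOX2, a transcription factor of the pluripotency network (chromosome 3, 182911639 to 182921638), carried H3K4me3 and no H3K27me3 enrichment. Its mean log2 ratio was 1.73 ± 0.43 for H3K4me3 (SD, n = 38 arrays) and -0.23 ± 0.11 for H3K27me3 (SD, n = 38). H3K4me3 was highest in the 500 bp from 182915139 to 182915638, at 2.94 ± 0.56, a 7.69-fold enrichment, where H3K27me3 stood at -0.52 ± 0.19. On the genome tiling, this region overlapped an H3K4me3 domain of 8 kb, from 182910001 to 182918000, which left the end of the region outside it. The region named after NANOG, another pluripotency factor (chromosome 12, 7828152 to 7838151), had 0.93 ± 0.30 for H3K4me3 and -0.53 ± 0.18 for H3K27me3 (SD, n = 38 each). Its H3K4me3 was highest from 7833652 to 7834151, at 2.51 ± 0.52, and the domain over it was 5 kb long. The region named after FGF4, which encodes a fibroblast growth factor (chromosome 11, 69290668 to 69300668), differed from both of these in carrying the 2 marks. It had 0.43 ± 0.27 for H3K4me3 and 0.67 ± 0.23 for H3K27me3 (SD, n = 38 each), and H3K27me3 lay above 0 on 38 of 38 arrays. The 2 marks reached their highest windows of this region next to each other, H3K4me3 at 1.59 ± 0.47 from 69299168 to 69299667 and H3K27me3 at 1.84 ± 0.38 from 69299668 to 69300167. On the genome tiling, 2 of its 8 bins of 1 kb were above 2-fold for H3K4me3, 2 for H3K27me3 and 0 for both. A window of 7 probes in the same region (69292168 to 69292667) stood at -2.50 ± 0.47 for H3K4me3, which lowers the mean of that mark.

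**Figure D1:**
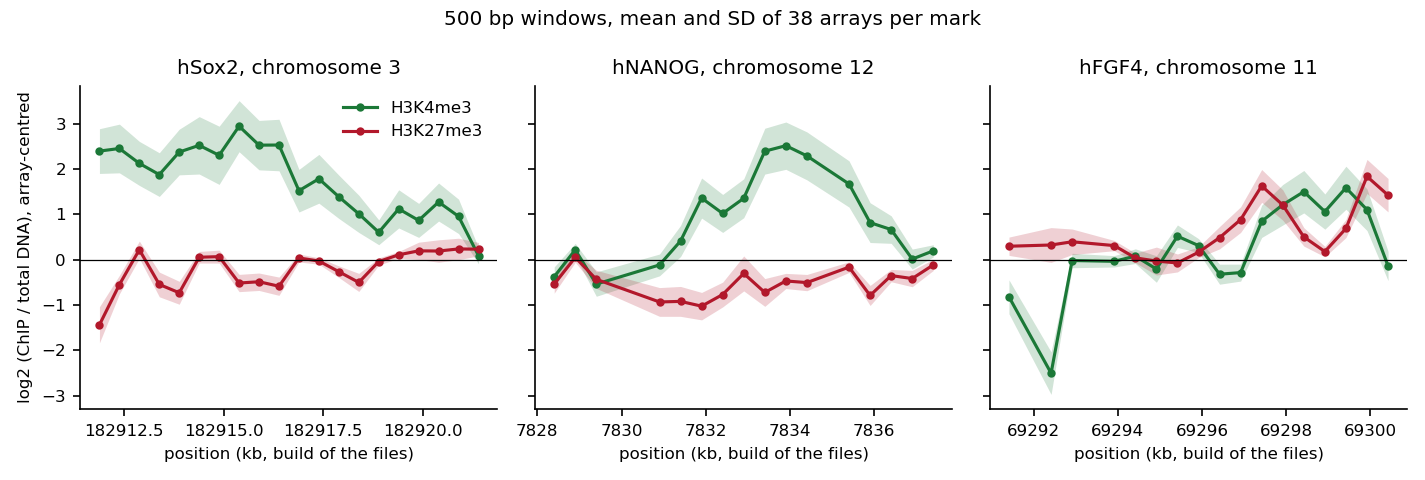
Log2 ratio (y axis) in 500 bp windows along the 3 control regions named after genes (x axis, kb), with the mean (points) and SD (shading) of 38 arrays for H3K4me3 (green) and H3K27me3 (red). H3K4me3 peaks at 2.94 over SOX2 and 2.51 over NANOG where H3K27me3 lies below 0, and over FGF4 both marks rise above 1.

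The other 7 control regions carry numbers in place of gene names. Region 009856 (chromosome 1, 146620480 to 146630480) had the largest contrast, with 1.87 ± 0.44 for H3K4me3 and -0.99 ± 0.25 for H3K27me3. Regions 002903 on chromosome 18 and 018939 on chromosome 3 also carried H3K4me3 alone, at 0.95 ± 0.21 and 1.01 ± 0.24. Regions 005131 (chromosome 9, 76853439 to 76863435) and 018543 (chromosome 7, 8245077 to 8255077) carried both marks. Region 005131 had 1.39 ± 0.37 for H3K4me3 and 1.33 ± 0.30 for H3K27me3, and region 018543 had 1.34 ± 0.36 and 1.17 ± 0.31. In these 2 regions, each mark was above 0 on 38 of 38 arrays. Region 005183 on chromosome 9 had 0.04 ± 0.30 for H3K4me3 and 0.43 ± 0.28 for H3K27me3, with highest windows of 1.25 ± 0.48 (125250090 to 125250589) and 1.41 ± 0.38 (125249090 to 125249589). Region 006470 on chromosome 10 lay near 0 for both marks, at -0.0049 ± 0.09 and -0.12 ± 0.05 (all SD, n = 38 arrays per mark).

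The log2 ratios of the 2 marks differed in 9 of the 10 control regions (two-sided permutation test, 38 arrays against 38, Benjamini-Hochberg adjustment over the 10 regions). The ratios come from separate precipitations, each centred on its own array median, so they need not share a scale. Region 006470, near 0 for both marks, was among the 9 (difference 0.11, adjusted p 1.4e-05 in this test). A difference alone therefore does not say which mark a region carries. H3K4me3 exceeded H3K27me3 by 1.96 over SOX2 and by 1.47 over NANOG, on 38 of 38 arrays set side by side by number, with an adjusted p of 1.4e-05, the smallest these permutations can give after adjustment. Over FGF4 the difference was -0.24, with H3K27me3 higher on 25 of 38 arrays, and the adjusted p was 8.7e-05 in the permutation test. It was 0.06 in region 005131, where the permutation test gave an adjusted p of 0.4120. In region 018543 it was 0.17, with H3K4me3 higher on 24 of 38 arrays and an adjusted p of 0.0300 in the same test. The array numbers do not pair the arrays, so counts below 38 of 38 depend on which arrays are set side by side. With the number series in the scanner headings as a random block in limma, the adjusted p was 3.1e-02 over FGF4 and 4.4e-01 in region 018543, which ended the call there. Nothing in the labels says that the arrays come from separate cultures, so these p-values measure only the spread between hybridisations.

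**Figure D2:**
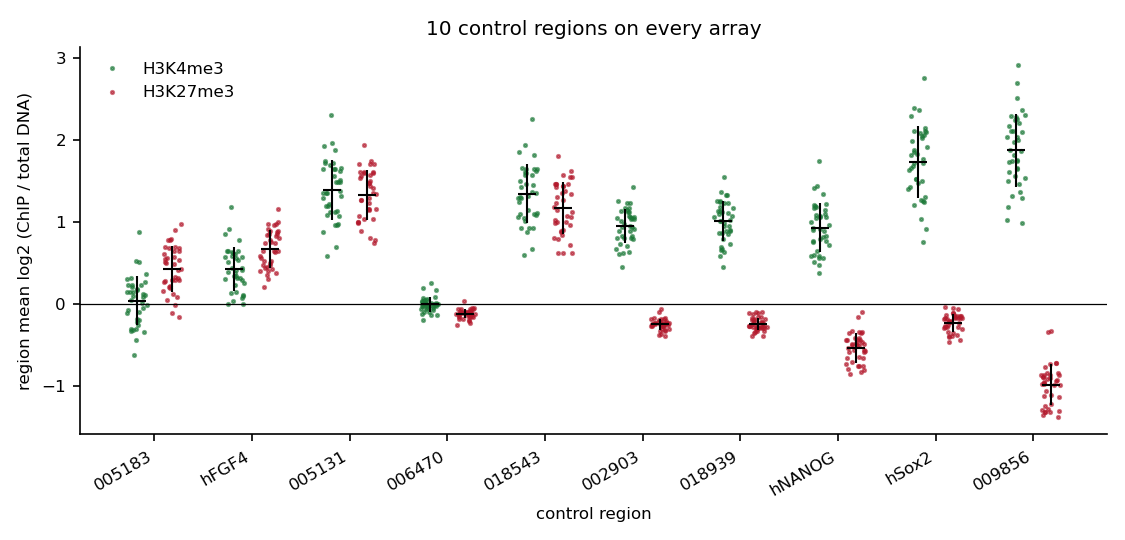
Mean log2 ratio (y axis) of each of the 10 control regions (x axis, ordered by the difference between the marks) on each array (dots) for H3K4me3 (green) and H3K27me3 (red), with the mean and SD of 38 arrays (black). Regions 005131 and 018543 lie above 0 for both marks on all 38 arrays per mark, and region 009856 has the widest gap, 1.87 against -0.99.

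Across the genome, the question was how much of it each mark covers and where the 2 marks meet. At a threshold of 2-fold, 39388 of 1654324 measured bins of 1 kb (2.38%) carried H3K4me3 and 22810 (1.38%) carried H3K27me3. On single arrays, which hold different parts of the genome, the share ran from 0.36% to 4.76% for H3K4me3. For H3K27me3 it ran from 0.08% (array 8) to 5.57% (array 36). In the deposited values these 2 arrays had 0.51% and 1.65%, so the share of an array depends on the normalization. Both marks were found in 5508 bins, which made up 24.1% of the H3K27me3 bins and 14.0% of the H3K4me3 bins. If the 2 sets of bins were placed independently, 543 bins would be shared. Sliding the H3K27me3 bins along each chromosome gave 655 shared bins in the mean of 1000 shifts and 804 at most. The excess over the product, 10.1 times, was 2.23 times within strata of total DNA intensity. With each mark set against the total DNA of the other set it was 1.87 times. That swap adds the difference between the total DNA channels to the 2 marks with opposite signs, which lowers the overlap by construction. Shared bins numbered 2908 with arrays centred on the random-sequence probes and 9130 with loess within arrays. These were 9.39 and 12.8 times the product of the shares in the same settings. These arrays give 1 measurement per mark and bin, so no test between replicates applies. The rule set before the data were examined, which weighs bins above a threshold against bins as far below 0, called 0 bins for either mark, and the 2-fold threshold was chosen after that result was seen. Bins below a 2-fold depletion numbered 57755 for H3K4me3 and 23170 for H3K27me3, so the 2-fold counts carry no error rate from the negative side.

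Odd and even probes gave 2 estimates of each bin from the same hybridisation. Agreement between them covers noise between probes only, and says nothing of repeat arrays, precipitations or cultures. The means of odd and even probes correlated at r = 0.825 over 1426771 bins for H3K4me3 and at r = 0.830 for H3K27me3 (across bins, which are not independent replicates). Of the bins above 2-fold on odd probes, 89.5% were so on even probes for H3K4me3 and 79.7% for H3K27me3. The median standard error of a bin mean over its probes was 0.15 for H3K4me3 and 0.11 for H3K27me3. This error has the same limit, and it takes neighbouring probes as independent.

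H3K4me3 was focal. Joined over gaps of up to 1 kb, its bins made 17442 domains with a median length of 2 kb, of which 101 reached 10 kb (251 when joined over gaps of up to 3 kb) and 0 reached 50 kb in either case. The strongest domain of at least 3 kb lay on chromosome 8 from 31009001 to 31012000, with a mean log2 ratio of 3.35 (SD over probes 0.63, 21 probes) for H3K4me3 and 0 kb above 2-fold for H3K27me3. The 10 strongest domains had H3K4me3 means from 3.04 to 3.35, and none of them held a bin above 2-fold for H3K27me3, where shifts gave 0.15 of the 10 in the mean, so domains this short would rarely hold one by position alone. With the deposited values or with arrays scaled on the control regions, 0 of these 10 were among the 10 strongest, so the order of the strongest domains rests on the scaling of arrays. The longest H3K4me3 domain covered 41 kb on chromosome 1 (225050001 to 225091000, mean 1.38, SD over 278 probes 0.37), with a mean of 0.77 in the deposited values. The next covered 27 kb on chromosome 13 (99416001 to 99443000, mean 1.82, SD over 258 probes 0.85) and 19 kb on chromosome 14 (56331001 to 56350000, mean 2.14, SD over 188 probes 0.92). The 10 longest H3K4me3 domains all held H3K27me3, over 1 to 17 kb of their length, against 0.83 of the 10 in the mean of 100 shifts of the H3K27me3 bins and 4 at most. They include the domain of 41 kb, which held 1 H3K27me3 bin and may be a repeat, as described under other observations. Of these 10, 4 were among the 10 longest in the deposited values and 6 were with arrays scaled on the control regions. The longest domain in the deposited values had 29 kb and lay on chromosome X.

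H3K27me3 was broader. It formed 9029 domains with a median length of 1 kb, but 401 of them reached 10 kb and held 25.5% of its bins, against 3.04% for H3K4me3. Joined over gaps of up to 3 kb, 679 did and held 41.4%, against 6.72% for H3K4me3, and the longest grew from 141 to 240 kb. Domains of 141 kb on chromosome 12 (52603001 to 52744000), 114 kb on chromosome 2 (176756001 to 176870000) and 107 kb on chromosome 7 (26900001 to 27007000) were the longest, and the next had 48 kb. Their mean H3K27me3 log2 ratios were 1.90 (SD over 1349 probes 0.71), 1.87 (SD over 1062 probes 0.71) and 1.88 (SD over 1030 probes 0.73). H3K27me3 was above 2-fold in 138, 108 and 104 of their bins. H3K4me3 averaged 0.37, 0.27 and 0.33 in them, and was above 2-fold in 13, 13 and 9 bins. The domain of 48 kb lay on chromosome 19 (12965001 to 13013000), followed by 46 kb on chromosome 2 (219543001 to 219589000). The domain with the highest mean lay on chromosome 22 (17530001 to 17533000), at 2.43 (SD over 28 probes 0.48), a 5.39-fold enrichment, but 2 of the 10 domains with the highest means were among those 10 in the deposited values and 0 with arrays scaled on the control regions. The number of domains of at least 50 kb, 3 here, was 3 on odd probes, on even probes, in the deposited values and with arrays scaled on the control regions, 4 with arrays scaled to one MAD and 20 when bins were joined over gaps of up to 3 kb, so it depends on the join. Of the 10 longest domains, 8 were among the 10 longest in the deposited values and 7 were with arrays scaled on the control regions.

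**Figure D3:**
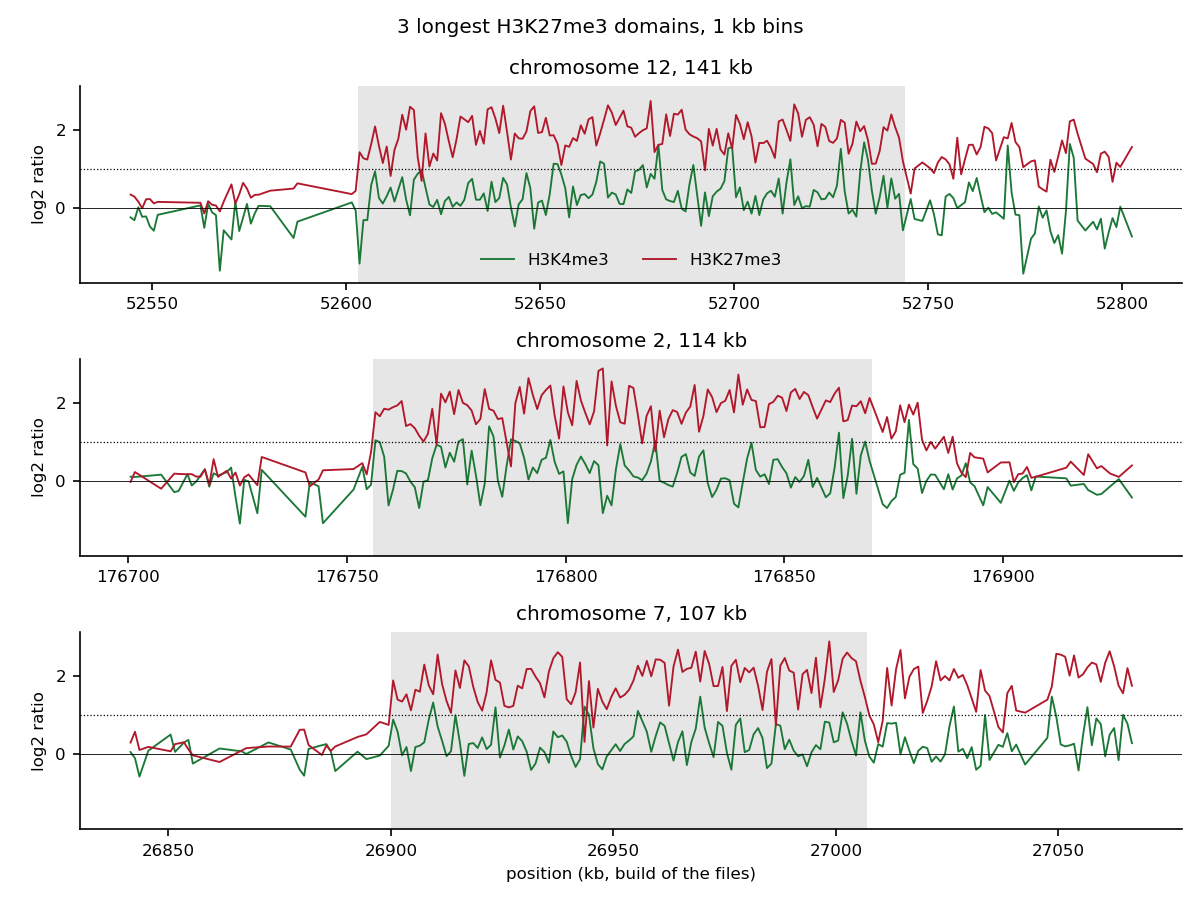
Log2 ratio (y axis) in 1 kb bins along the 3 longest H3K27me3 domains and their surroundings (x axis, kb) for H3K27me3 (red) and H3K4me3 (green), with the domain shaded and the 2-fold threshold dotted. H3K27me3 is above 2-fold in 138, 108 and 104 bins of the domains of 141, 114 and 107 kb, and H3K4me3 in 13, 13 and 9 bins.

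H3K27me3 domains held H3K4me3 more often the longer they were. The share rose with length under shifts of the H3K4me3 bins too, since longer domains have more bins in which to hold one. Of 4802 domains of 1 kb, 19.3% held an H3K4me3 bin, against 2.86% in the mean of 100 shifts. Of 322 domains of 10 to 19 kb, 71.7% did, against 14.5%, and of 79 domains of 20 kb or more, 71 did (89.9%), against 25.4%. Even in the longest class, the median domain carried H3K4me3 in 19.4% of its bins. Of the 17442 H3K4me3 domains, 3078 (17.6%) held an H3K27me3 bin. Among these, 15.7% were at least 5 kb long, against 9.37% in the mean of 100 shifts and 13.5% at most, a comparison that allows for longer domains having more bins in which to hold one. The longest stretch with both marks covered 17 kb on chromosome 10 (94809001 to 94826000), where H3K4me3 averaged 2.08 (SD over 146 probes 0.95) and H3K27me3 1.87 (SD over the same probes 0.68). Stretches of 17 kb followed on chromosome 11 (31782001 to 31799000) and chromosome 6 (10518001 to 10535000), with H3K4me3 at 1.85 and 2.16 and H3K27me3 at 1.68 and 1.78. The stretch of at least 3 kb with the highest level of the lower mark lay on chromosome 12 (56444001 to 56447000), with H3K4me3 at 2.22 (SD over 30 probes 0.49) and H3K27me3 at 2.31 (SD 0.47). Of the 10 longest stretches, 2 were among the 10 longest in the deposited values and 5 were with arrays scaled on the control regions. Of the 10 with the highest levels, 2 and 1 were.

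H3K27me3 did not rise steadily with H3K4me3. In the 14659 bins with an H3K4me3 log2 ratio of 1 to 1.5, the median H3K27me3 was 0.12 and 16.6% of bins were above 2-fold. In the 3970 bins above 2.5, the median was -0.37, 7.81% were above 2-fold and 21.6% were below a 2-fold depletion. For the same 3970 bins, the median ran from -0.42 with arrays scaled on the control regions to -0.24 with loess within arrays. With the group above 2.5 formed anew from the H3K4me3 values of the setting, other bins enter it, and the median was -0.76 (1746 bins) and -0.03 (14216 bins). Around the summits of H3K4me3 domains, the median H3K27me3 was -0.07 at the summit bin, 0.13 at 2 kb upstream in coordinates and -0.01 at 10 kb. In the deposited values and with loess the summit bin had 0.02 and the bin 2 kb upstream 0.16. The sign over all summits thus depends on the normalization, while the summit lay below the bin 2 kb upstream in each of these settings. At the 7067 summits with an H3K4me3 log2 ratio above 2, the median H3K27me3 was -0.32, against -0.20 in the deposited values and -0.19 with loess. Over all bins the marks correlated at Pearson r = 0.172 and Spearman rho = 0.290 (across bins, which are not independent replicates), and rho was 0.144 with loess and 0.150 in the deposited values. Within arrays, r had a median of 0.166 and ran from -0.21 to 0.54, below 0 on 3 of 38 array numbers. With each mark set against the total DNA of the other set, r turned to -0.424. The difference between the total DNA channels enters these ratios with opposite signs, which lowers r by construction.

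**Figure D4:**
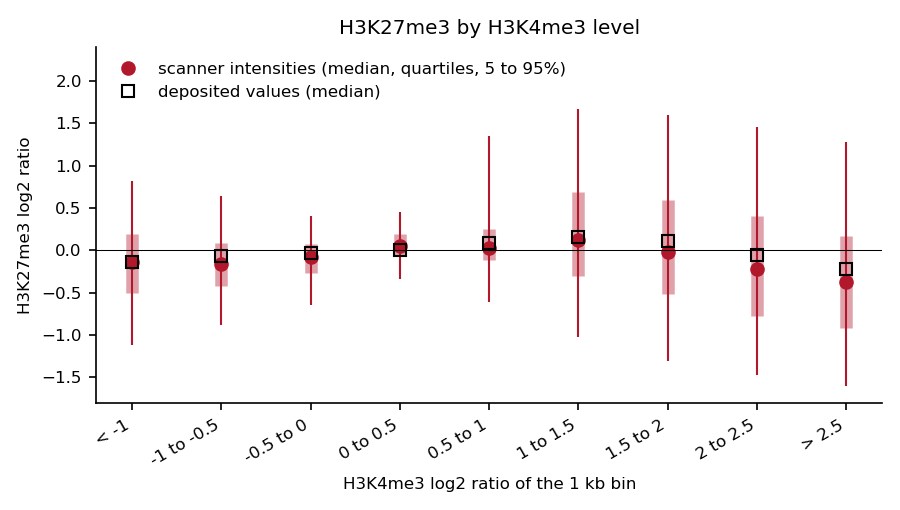
H3K27me3 log2 ratio (y axis) of 1 kb bins grouped by their H3K4me3 log2 ratio (x axis), as median (red points), quartiles (bars) and 5th to 95th percentile (lines), with medians of the deposited values as open squares. The median is 0.12 in the group from 1 to 1.5 and -0.37 in the group above 2.5.

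Both marks covered more of the gene-dense chromosomes. On chromosome 19, 7.54% of bins carried H3K4me3 and 5.67% carried H3K27me3. On chromosome 17 the values were 5.92% and 2.32%, and on chromosome 4 they were 1.42% and 0.436%, the latter 1.03% in the deposited values. Chromosome 22 had 7.07% for H3K27me3, against 3.18% in the deposited values and 4.20% with arrays scaled on the control regions. Chromosome 19 had 4.41% and 3.99% in these settings, so which of the 2 is highest depends on the normalization. Over 22 autosomes and chromosome X (n = 23), the share of H3K4me3 bins rose with the number of protein-coding genes of the chromosome, counted in the GRCh38.p14 table, per measured Mb (r = 0.91, permutation p 1.0e-05, adjusted over 4 relations 4.0e-05, rho = 0.67, permutation p 6.3e-04, adjusted 0.0014). For H3K27me3, r was 0.68 (permutation p 0.0064, adjusted 0.0085) and rho was 0.68 (permutation p 6.8e-04, adjusted 0.0014). For bins with both marks, r was 0.69 (permutation p 1.9e-04, adjusted 3.8e-04) and rho 0.53 (permutation p 0.0102, adjusted 0.0104), but in the deposited values rho was 0.35 (permutation p 0.0981), which ended that call. The shares of the 2 marks correlated with each other at r = 0.56 (permutation p 0.0148, adjusted 0.0148) and rho = 0.53 (permutation p 0.0104, adjusted 0.0104). Without chromosomes 19 and 17, r was 0.70 for H3K4me3 (permutation p 3.6e-04) and 0.67 for H3K27me3 (permutation p 0.0014). It fell to 0.40 for both marks (permutation p 0.0738) and to 0.43 between the marks (permutation p 0.0600), so these 2 relations rest on chromosomes 19 and 17, although with arrays scaled on the control regions r for both marks was 0.71 without them (permutation p 3.4e-04). Chromosomes lie on different arrays. The share of bins and the gene density are both divided by the measured bins of a chromosome, while genes are counted over its whole length. What this shared divisor adds to the relations with gene density was not tested.

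The share of bins above 2-fold on each array was also set against the response of each array to the control regions (n = 38 arrays per mark). For H3K27me3, r was 0.44 (permutation p 0.0080, adjusted over 2 relations 0.0102) and rho was 0.57 (permutation p 2.3e-04, adjusted 4.6e-04). It was 0.49 without the 2 arrays of most unusual response, and 0.53, 0.51 and 0.50 within the 3 number series of at least 6 arrays. For H3K4me3, r was 0.41 (permutation p 0.0102, adjusted 0.0102) and rho was 0.36 (permutation p 0.0259, adjusted 0.0259). Without the 2 arrays of most unusual response r was 0.23 (permutation p 0.1805), and within the 4 number series of at least 6 arrays it was 0.91, 0.22, -0.50 and 0.20, so it was strong within 1 series and not within the other 3.

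**Figure D5:**
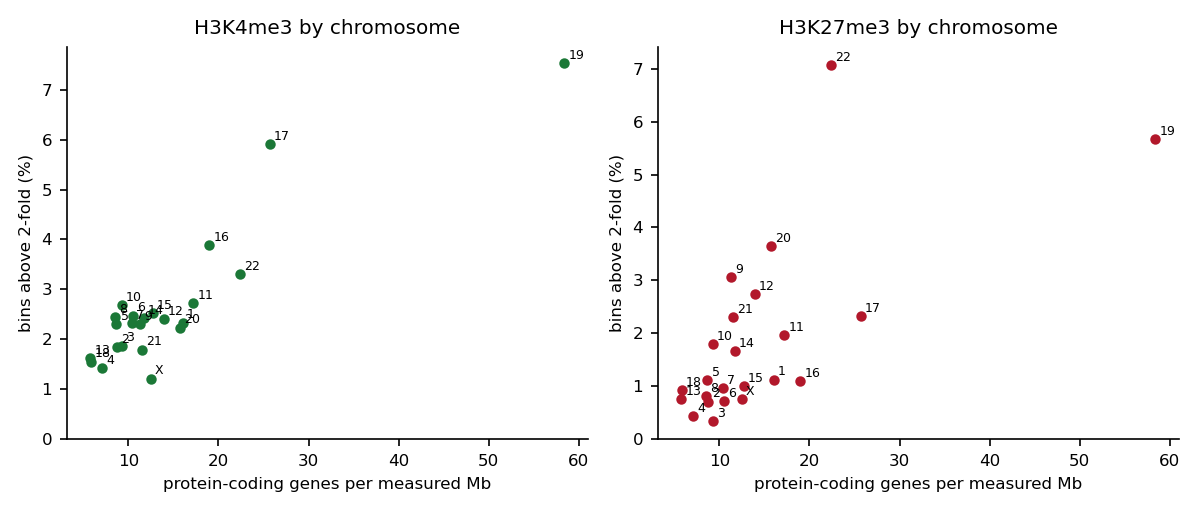
Share of 1 kb bins above 2-fold (y axis, %) for H3K4me3 (left) and H3K27me3 (right) against protein-coding genes per measured Mb (x axis), 1 point per chromosome for 22 autosomes and X. Chromosome 19 has 7.54% for H3K4me3, and chromosome 22 has 7.07% for H3K27me3, which falls to 3.18% in the deposited values.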

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

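No test was run on the results in this part. Probes of random sequence served above only to centre arrays in alternative settings. Sequences not placed on a chromosome were counted among the bins but left out of the chromosome relations. An offset of the random-sequence probes from the tiling probes is no measure of either mark. The random-sequence probes, 776 on most arrays, had a median log2 ratio above the median of the tiling probes, 0.25 in the median of 38 H3K4me3 arrays and 0.2 in that of 38 H3K27me3 arrays. It was above 0 on 38 of 38 H3K4me3 arrays, from 0.03 to 0.70, and on 36 of 38 H3K27me3 arrays, from -0.06 to 0.53. Means of 9 random-sequence probes passed 2-fold in 0.0053% of draws for H3K4me3 and 0.0184% for H3K27me3. On 19 sequences not placed on a chromosome, with 7942 bins, 4.0% of bins were above 2-fold for H3K4me3, against 2.37% elsewhere, and 1.52% for H3K27me3, against 1.38% elsewhere. In the deposited values these shares were 4.57% against 2.64% and 1.60% against 1.25%.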

How the results depend on the processing

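Chosen only after the results were seen were control-region scaling, random-sequence centring, the 2-fold, 1.5-fold and 3-fold thresholds, all settings for control regions, chromosomes, the strongest H3K4me3 bins and summits, the swapped total DNA for the overlap, and all but the within-array and swapped settings for the correlation.

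The planned calling rule gave 0 bins for both marks. It gave 41888 H3K4me3 bins with loess, 6961 H3K4me3, 957 H3K27me3 and 24 shared bins without the dimmest and brightest 1% of probes, 5412 H3K4me3 bins with MAD scaling, 47 in the deposited values, 7 with at least 8 probes, and 1 each with the median of probes, odd probes, even probes and 5 kb bins. H3K4me3 domains by that rule numbered 3284 with MAD scaling, 41 in the deposited values, and 1 each on odd and even probes. The cause was not tested.

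At 2-fold, 500 bp bins gave 75206 H3K4me3, 45744 H3K27me3 and 11382 shared bins, and 5 kb bins gave 7205, 4006 and 701, as the number of bins changes by construction. By construction too, 1.5-fold gave 61258, 62466 and 13489, and 3-fold gave 22332, 6227 and 913. Shared bins numbered 9130 with loess and 2908 with random-sequence centring. The excess over the product of the shares was 12.8 and 9.39 in these 2 settings and 5.83 at 1.5-fold. The cause of these moves was not tested. The excess was 1.87 with the total DNA swapped, where the total DNA channels enter the ratios of the 2 marks with opposite signs by construction. Joining over 3 kb took the longest H3K27me3 domain to 240 kb and the longest stretch with both marks to 32 kb, by construction. It also took domains of at least 10 kb from 101 to 251 for H3K4me3, from 401 to 679 for H3K27me3 and from 25 to 87 for both marks, and H3K27me3 domains of at least 50 kb from 3 to 20. In the deposited values, stretches of at least 10 kb with both marks numbered 49, and the cause was not tested. The total numbers of domains stayed within 1.5 times.

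The correlation of the marks, 0.172 by Pearson r, was 0.166 within arrays, 0.159 with loess, 0.166 in the deposited values and 0.163 with control-region scaling. Spearman rho, 0.290, was 0.258, 0.144, 0.15 and 0.218. With the total DNA swapped, r was -0.424 and rho -0.209. The total DNA channels differed by an SD of 0.48 over bins, against 0.49 and 0.38 for the ratios, and enter the swapped ratios with opposite signs by construction. Median H3K27me3 above an H3K4me3 log2 ratio of 2.5, -0.37, was -0.03 with loess, -0.22 in the deposited values, -0.76 with control-region scaling and -0.27 with MAD scaling when the bins were chosen anew in each setting, which changes their number by construction. For the same 3970 bins it was -0.24, -0.26, -0.42 and -0.38, the lowest of the 9 groups in each. At summits, -0.07 became 0.02 with loess, 0.02 in the deposited values and -0.11 with control-region scaling. The cause was not tested.

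Of the 9 control regions that differed, 8 did under each of 5 other settings, and region 018543 did not (differences of 0.13 to 0.19, adjusted p 5.1e-02 to 4.4e-01). With the array number as a block in limma, it had 0.17 and an adjusted p of 5.1e-02, and no other call changed. A sign-flip permutation test by array number gave it an adjusted p of 0.0562. The numbers do not pair the arrays: deviations of same-numbered arrays correlated between -0.84 and 0.55, with 9 of 38 above 0.1, and 1 of 38 H3K4me3 arrays correlated best with its own number. Pearson relations of chromosome shares to gene density kept their sign and calls in the deposited values and with control-region scaling, but rho for both marks in the deposited values was 0.35 (permutation p 0.0981). In the deposited values the share of chromosome 22 went from 7.07% to 3.18% for H3K27me3 and from 3.31% to 5.93% for H3K4me3, and the H3K27me3 share of chromosome 4 from 0.436% to 1.03%. With control-region scaling, chromosome 22 had 4.20% for H3K27me3. The cause was not tested. Leaving out replicates was not possible, and promoter and gene list alternatives and a turned sign were not run. What signal over background limits was not tested.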

Other observations

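Chosen only after the result was seen were the tests of intensity bias and of a few arrays for the strongest H3K4me3 bins, of arrays holding more of both marks and of HOX chromosomes, the shuffles of probe values, and the following of the same bins through the settings. No biological explanation was tested for the longest H3K4me3 domain, the strongest H3K4me3 bins or the excess of bins with both marks, since the design gives no group for one.

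The mitochondrial genome, which is not packaged in histones, was measured by 162 probes. Its median log2 ratio was -3.35 for H3K4me3 and -3.45 for H3K27me3. In the total DNA channel, 35.2% and 8.64% of these probes were saturated, so the ratios are upper bounds for those probes.

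A hypothesis is that the 3 longest H3K27me3 domains cover HOX clusters, which hold genes for transcription factors of body patterning. The 39 HOX genes in the GRCh38.p14 table lie on 4 chromosomes, numbers 2, 7, 12 and 17, and the 3 domains lie on 12, 2 and 7. Among 100000 random triples of the 401 H3K27me3 domains of at least 10 kb, 0.4% (percent of triples on 3 different chromosomes with HOX genes, the test of domains over HOX clusters) did so. The longest domain of chromosome 17 had 36 kb (44009001 to 44045000) and ranked 12. The test reads chromosomes only, so it cannot place any domain over a gene.

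The longest H3K4me3 domain may be a repeat. Its probes had a median total DNA intensity at the 98.8th percentile of the array, 40.0 times the array median, and at the 97.6th percentile on the array of the other mark, 9.497 times its median, so the fold gives no number of copies. Probe pairs 4470 bp apart correlated at 0.83 and pairs 2230 bp apart at 0.82, while the highest correlation at any spacing over 200 shuffles was 0.62. Both tests came out as a tandem sequence in many copies would have it, and the domain mean was 1.38 against 0.77 in the deposited values. Whether each copy carries H3K4me3 stays open.

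H3K27me3 lay lowest at the strongest H3K4me3 bins, and for the same 3970 bins it did so with loess (-0.24), MAD scaling (-0.38) and control-region scaling (-0.42) and in the deposited values (-0.26), although not with loess (-0.03) or MAD scaling (-0.27) when the bins were chosen anew. Within strata of total DNA intensity, of which 14 of 20 held enough bins, the median of bins above an H3K4me3 log2 ratio of 2.5 differed from that of bins from 0 to 0.5 by -0.44, and by -0.43 without strata, which argues against an intensity bias as the whole cause. Of 22 arrays with at least 20 such bins, 95.5% had a median below 0, so that sign was not confined to a few of these arrays. Arrays with fewer such bins were left out, and groups of H3K4me3 level were not compared within arrays. In the 3970 bins the difference from bins of 0 to 0.5 was -0.24 with loess and -0.27 in the deposited values, so its depth depends on the normalization. A lower density of histones at those bins was not tested and stays open.

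The excess of bins with both marks was 10.1 times the product of the shares. With H3K4me3 from odd and H3K27me3 from even probes it was 9.36, and with the expected count summed over arrays it was 9.07, which argues against effects of single probes and against arrays holding more of both marks. Within 400 strata of total DNA intensity in both sets it was 2.23, so a part that goes with the brightness of the sequence cannot be told apart from marks that share bright sequence. Whether both marks sit on the same DNA molecules cannot be read from separate precipitations.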
